A study of Mus musculus with 8 samples.

How the data were processed

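The data were RNA-seq libraries from the occipital cortex of mice, 4 fasted for 48 h and 4 fed ad libitum, with the group taken from each sample's treatment label and the replicate number from its title. Per the labels' protocols, the tissue was frozen in liquid nitrogen after dissection, RNA was extracted with a phenol and guanidine reagent and libraries followed Illumina's usual protocol. Per the submitters' processing notes, TopHat was used and the genome build was mm10; the version of TopHat, the program that quantified genes and the annotation are not given in the sources used here, nor whether the libraries keep strand. The deposited values are FPKM, in 1 table of 24883 rows with 1 column per library, and no scaling between libraries is stated.

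The table held 24344 distinct gene symbols. A further look at the rows showed 282 symbols on several rows (821 rows), of which the row with the highest mean over all libraries was used, 25 symbols turned into dates by spreadsheet software, which were kept as they stand, and 0 mitochondrially encoded genes. Of the symbols, 23949 matched the GENCODE M21 annotation (GRCm38, the same assembly as mm10), from which coordinates, GC content and transcript lengths were taken. FPKM do not give depth directly. It was estimated from FPKM times transcript length in 3038 genes with a single transcript. The value where low products lay densest was taken as that of 1 fragment, with 69 to 98 genes per library at this point. The search was confined to a range fixed beforehand, which bounds the estimate. A much deeper library, with the step of several fragments in that range, would be read as shallower, so the estimate is uncertain. It came to 17600000 to 21400000 fragments per library, so that 1 FPKM on a 2 kb transcript stood for 35.2 to 42.8 fragments. FPKM totals ranged from 254085.8 to 640016.8, the latter in ad libitum replicate 2.

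The design written before the data were examined named a count test first and a fallback for normalized units. Since the values are FPKM, the fallback was used: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with genes kept at 1 FPKM or more in at least 4 libraries and group as the only term. Moderation was by empirical Bayes with a trend in the mean and robust estimation (limma-trend). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Of tested genes 99.3% had a GC value. Gene sets were tested with limma's camera at a preset inter-gene correlation of 0.01. The p-values were adjusted over the 43 lists with at least 3 measured members, of those fixed in advance. Choroid plexus and ependyma, with 1 measured gene, peripheral leukocytes, with 0, and mitochondrially encoded genes, with 0 in the table, were not tested. Library measures were compared by an exact two-sided permutation test over all 70 assignments. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.

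The genes named were chosen by a rule fixed in advance: the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 FPKM and no overlap between the groups; from each list described, up to 4 called members with the smallest p, or the 2 with the smallest p where none was called; and a fixed set that holds Bdh1, Oxct1, Slc16a1, Fkbp5, Sgk1, Pdk4, Per1, Per2, Dbp, Cirbp, Npy and Fos. A few genes are not reported here and were left out of the search for libraries far from the rest of their group. Genes named outside this rule are said to have been chosen after their values were seen, and the microglial complement genes in the report are among them.

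The steps were tested on simulated data for the fasted against ad libitum comparison, with 12377 genes drawn from the observed means and residual SDs and 200 genes changed by a known fold. The gene test recovered 6.5% of genes changed 1.2-fold, 81% of those changed 1.5-fold and 95.5% of those changed 2-fold, with 0, 5 and 10 false calls, and made 0 calls with no gene changed. In 200 lists of 15 genes, camera called 20 of 20 lists shifted by 0.2 on the log2 scale and 0 others. The simulated genes were independent of each other, which real genes are not. Far fewer genes were changed than the 3198 called in the data, which makes the adjusted threshold stricter. The shares recovered thus do not give the sensitivity of the real comparison.

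The replicate numbers are shared between the groups, and whether they pair libraries was checked from the deviations of each library from its group mean. Same-numbered libraries correlated at 0.574, 0.496, 0.382 and 0.523 over all tested genes and at 0.354, 0.183, 0.119 and 0.354 over 11492 autosomal protein-coding genes (correlations across genes, which are not independent replicates). All exceed 0.1, which was the bound set for taking the numbers as pairing the libraries, from the data and not from a label. The sign is weak over autosomal genes, where libraries with different numbers correlated at up to 0.240 (ad libitum replicate 4 with fasted replicate 3), with 0.233 for ad libitum replicate 2 and fasted replicate 1 and 0.126 for ad libitum replicate 1 and fasted replicate 2. Over all tested genes the highest value between different numbers was 0.381, for ad libitum replicate 1 and fasted replicate 3. There, different numbers that were both odd or both even correlated at 0.165 to 0.381, and odd with even numbers at -0.546 to -0.256. The values over all genes thus partly follow odd and even numbers and are weak evidence of pairs. Over autosomal protein-coding genes the second principal component (21.2% of the variance) followed the replicate numbers in order in both groups. It was 7.86, 4.72, -2.67 and -15.18 in ad libitum replicates 1 to 4 and 8.27, 5.08, -1.8 and -6.29 in the fasted ones. The main fit, with group as the only term, leaves this difference in the spread within groups. The alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 FPKM, estimation without robustness, the replicate number as a block, offsets by per-library loess on GC content and length with and without the block, each library left out, and, for lists, an estimated correlation and the rotation test fry. Chosen after seeing the data were median-ratio, equal-sum and quantile scaling, a term for odd and even numbers, leaving out symbols on several rows, the estimated correlation with the block and, for library measures, an exact test over the 16 sign flips within the replicate numbers. The same flips were used for the microglial markers. A blocked fit and t-tests of each marker against the mean of the markers were tried and set aside: the former had an error shared by all genes, and 4 pairs are too few for the latter.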

Results

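RNA was sequenced from homogenates of the occipital cortex, the part of the neocortex that holds the visual areas, of C57BL/6J mice at postnatal day 35. The 8 libraries fell into 2 groups of 4, mice kept without food for 48 h and mice fed ad libitum. The values were FPKM (fragments per kilobase of transcript, relative to the fragments mapped). The estimated depth was 17600000 to 21400000 fragments per library, so that 1 FPKM on a transcript of 2 kb stood for 35.2 to 42.8 fragments. Both values come from a search confined to a fixed range, in which a much deeper library would be read as shallower, and are uncertain. Between 12223 and 12445 genes reached 1 FPKM in a library. Fasted libraries had a mean of 12280.5 such genes ± 44.0 (SD, n = 4) and fed libraries 12361.5 ± 78.2 (SD, n = 4). The difference was -81 (exact two-sided permutation test, p = 0.1429), and -115.8 without ad libitum replicate 4 (p = 0.0286, the same exact test). Within the replicate numbers 1 to 4 the fasted library was lower each time, by 34, 147, 109 and 34 genes (exact sign-flip test, p = 0.125, the smallest that 4 pairs can give). Estimated depth differed by 400000 fragments (exact two-sided permutation test, p = 0.7143), by -308333 without fasted replicate 3 and by 958333 without fasted replicate 2. The FPKM total differed by -93787.7 (p = 0.4, exact permutation test) and by -4898.68 without ad libitum replicate 2. The share taken by the 10 most abundant genes differed by -2.88 percentage points (p = 0.3143, exact permutation test). Within the replicate numbers 1 to 4 it differed by -0.11, -3.8, -7.6 and -0.02 points (exact sign-flip test, p = 0.125). The group difference in this share was -1.308 without ad libitum replicate 2 and -1.278 without ad libitum replicate 3. It was -4.445 without ad libitum replicate 1 and -4.498 without ad libitum replicate 4.

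The comparison of the groups asks which transcripts of the cortex differ after 48 h without food, in a series whose title concerns the histone mark derived from the ketone body beta-hydroxybutyrate. Fasted cortex had higher levels of most measured genes known to respond to glucocorticoid hormone, among them Fkbp5, Sult1a1, Hif3a and Sgk1. It also had higher levels of the cold-inducible RNA-binding protein genes Cirbp and Rbm3 and of several genes of the circadian clock. It had lower levels of part of the genes for sterol synthesis (14 of 23) and fatty acid synthesis (8 of 13), of the unfolded protein response (11 of 16) and heat shock (9 of 17) lists, and of the microglial markers (6 of 14). As sets these lists passed the test with a preset correlation between genes and did not pass with an estimated one. With 8 libraries the latter test has less power, also where the estimated correlation is low. Of 10 measured genes of ketone body use and transport 3 were lower, among them Oxct1 and Slc16a7. Another 2 were higher, among them Slc16a1, and the list did not move as a set. In all, 3198 of 12377 tested genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 1183 higher and 2015 lower in fasted cortex. By at least 1.5-fold 89 genes were higher and 101 lower, on the scale of log2(FPKM + 1), which understates the change of low genes. The values of the groups did not overlap for 27.6% of tested genes, where chance gives 2.9%.

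The balance of higher and lower genes depended on how libraries were scaled. It was 1740 higher and 1956 lower after median-ratio scaling, 1430 and 1967 after equal-sum scaling, 1792 and 1909 after quantile scaling, and 2228 and 2217 with offsets for GC content and transcript length. No gene called both with and without one of these steps changed direction, which is nearly assured when both fits use the same libraries. Ad libitum replicate 3 held both Xist and Y-linked transcripts at intermediate levels, and without it 841 genes were higher and 1406 lower. Odd and even replicate numbers part the libraries with Y-linked transcripts from those without. With a term for odd and even numbers 1154 genes were higher and 1989 lower. With the replicate number as a block 1773 were higher and 2733 lower.

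**Figure D1:**
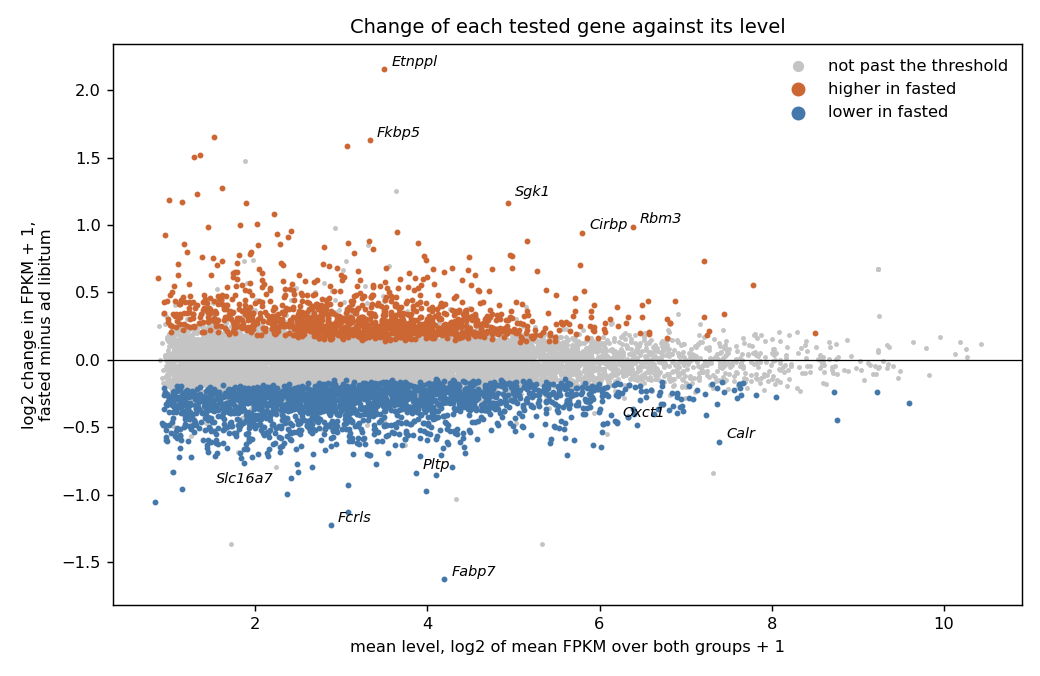
Change of each of the 12377 tested genes (y axis, log2 change in FPKM + 1, fasted minus ad libitum) against its level (x axis, log2 of the mean FPKM of both groups + 1). Coloured points are the 1183 genes higher and the 2015 genes lower in fasted cortex; Etnppl, with a log2 change of 2.15, lies highest and Fabp7, at -1.63, lies lowest.

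Among genes without overlap between the groups and with a mean of at least 1 FPKM, the largest rise was that of Etnppl (chromosome 3, 130617448 to 130637521), which encodes an ethanolamine-phosphate lyase found in astrocytes. It went from 3.17 FPKM ± 0.651 (SD, n = 4) to 17.4 ± 1.06 (SD, n = 4), a log2 change of 2.15 with SE 0.0978 and limma adjusted p = 9.6e-07. The chemokine gene Ccl17 rose by 1.65 on the log2 scale, from 0.389 to 3.34 FPKM, and Wnt10b, which encodes a secreted WNT ligand, by 1.501, from 0.271 to 2.63 FPKM. Fkbp5, Sult1a1 and Hif3a were also among the 10 largest rises and are described with the glucocorticoid-responsive genes. The long non-coding RNA gene 1810020O05Rik rose by 1.23 and Nanos2, which encodes an RNA-binding protein known from germ cells, by 1.17, both from fed levels under 1 FPKM (0.501 and 0.367). Alox12b, which encodes a lipoxygenase of the epidermis, rose by 1.16, from 1.29 to 4.12 FPKM. It lies on chromosome 11 at 69156989 to 69169792, next to Aloxe3, a gene chosen after its values were seen, which rose by 0.52 (adjusted p = 0.0028), and near Per1 at 69095217 to 69109960. Ccl21b, a chemokine gene with near-identical copies and a symbol on several rows of the table, had a log2 change of 1.52 with adjusted p = 0.0057, and 0.0534 with the replicate number as a block. Over all settings its adjusted p ran from 0.000852 to 0.0534, so that its value is uncertain.

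The largest fall was that of Fabp7 (chromosome 10, 57784881 to 57788450), the fatty acid-binding protein of astrocytes and their precursors, from 26.7 FPKM ± 4.42 (SD, n = 4) to 7.90 ± 0.574 (SD, n = 4), a log2 change of -1.63 with SE 0.0990 and limma adjusted p = 9.54e-06. The microglial genes Fcrls and Olfml3 had log2 changes of -1.23 and -1.13. Apln, which encodes the peptide ligand apelin, went from 5.88 to 2.45 FPKM. The phospholipid transfer protein gene Pltp went from 17.7 to 9.44 FPKM, the kinase gene Pak7 from 21.1 to 11.2 and the sulfurtransferase gene Tst from 10.1 to 4.80. Zfp950 had a log2 change of -0.97 and Gkn3 of -0.96. Slc16a7, which encodes the monocarboxylate transporter MCT2, went from 5.92 to 2.79 FPKM, a log2 change of -0.87.

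**Figure D2:**
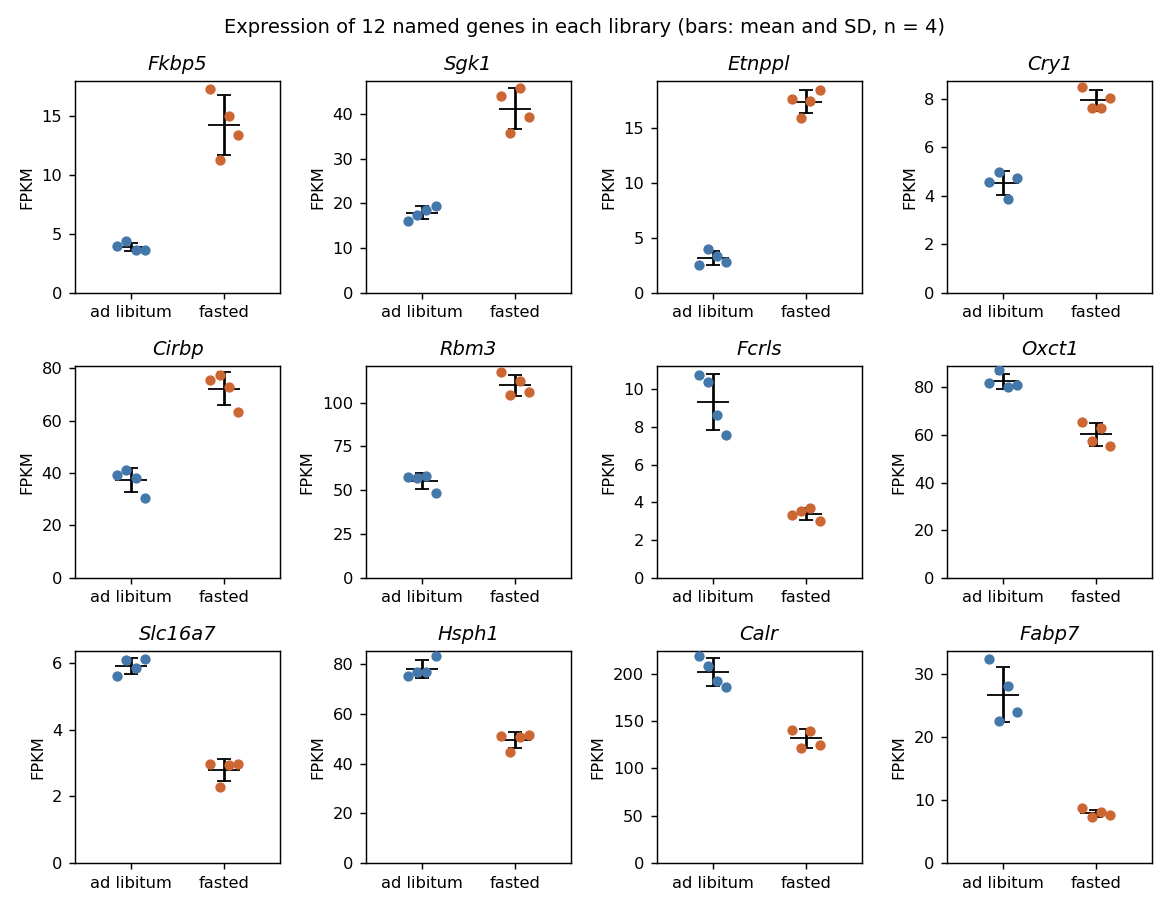
FPKM (y axis, from 0) of 12 named genes in the 4 ad libitum and the 4 fasted libraries, 1 point per library, with the mean and SD as bars. The groups do not overlap in any panel; Fkbp5 goes from a mean of 3.89 to 14.2 FPKM and Fabp7 from 26.7 to 7.90 FPKM.

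Glucocorticoid-responsive genes rose. Of 18 measured members of this list 16 rose and none fell (17 and 0 adjusted over the list alone), with a median log2 change of 0.81. Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor, went from 3.89 FPKM ± 0.352 (SD, n = 4) to 14.2 ± 2.55 (SD, n = 4), a log2 change of 1.63. The sulfotransferase gene Sult1a1 rose by 1.59 on the log2 scale, Hif3a by 1.27, and the kinase gene Sgk1 by 1.16, from 17.9 to 41.2 FPKM. As a set the list moved up against the other genes (limma camera, preset correlation, adjusted p = 1.37e-17), and adjusted p = 0.201 with an estimated correlation.

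In the core loop of the circadian clock 10 of 17 genes rose and 1 fell, and the numbers were 10 and 1 adjusted over the list alone. The repressor genes Cry1 and Cry2 rose by 0.69 and 0.43 on the log2 scale and Bhlhe41 by 0.32, while Rorb, a nuclear receptor gene of cortical layer neurons, had a log2 change of -0.39. Per1 rose by 0.77 (limma adjusted p = 0.017), from 22.5 FPKM ± 7.26 (SD, n = 4) to 37.9 ± 3.28 (SD, n = 4). It was at adjusted p = 0.055 without ad libitum replicate 2, 0.0561 without fasted replicate 4, 0.0553 with GC and length offsets and 0.0625 with equal-sum scaling, in a range over all settings from 0.00149 to 0.0625. Per2 rose by 0.48. Of the 4 clock output genes 1 fell (1 rose and 1 fell adjusted over the list alone, and also with the replicate number as a block), Dbp, with a log2 change of -0.27 and adjusted p = 0.0358. This call ended with no filter on low genes (adjusted p = 0.0636) and when any of 5 of the 8 libraries was left out, with adjusted p between 0.0815 and 0.0988 for those 5. The core loop moved up as a set (camera adjusted p = 3.49e-04; adjusted p = 0.201 with an estimated correlation).

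Genes known as FoxO targets or induced by fasting rose in 8 of 18 cases and fell in 1 (8 and 1 adjusted over the list alone). Klf15, which encodes a transcription factor of amino acid breakdown, rose by 0.79 on the log2 scale, Txnip by 0.68, Sesn1 by 0.55 and Pdk4, the kinase that inhibits pyruvate dehydrogenase, by 0.44, from 2.82 FPKM ± 0.0448 (SD, n = 4) to 4.18 ± 0.271 (SD, n = 4). The set test gave adjusted p = 4.17e-04 (camera), and adjusted p = 0.338 with an estimated correlation. Of the 4 cold-inducible RNA-binding protein genes 3 rose and 1 fell, also adjusted over the list alone. Rbm3 went from 55.2 FPKM ± 4.72 (SD, n = 4) to 110.0 ± 5.94 (SD, n = 4) and Cirbp from 37.2 ± 4.59 to 72.3 ± 6.16 (SD, n = 4 each), log2 changes of 0.98 and 0.94. Srsf5 rose by 0.34 and Rbm14 had a log2 change of -0.34. The set moved up (camera adjusted p = 0.0254; adjusted p = 0.576 with an estimated correlation).

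**Figure D3:**
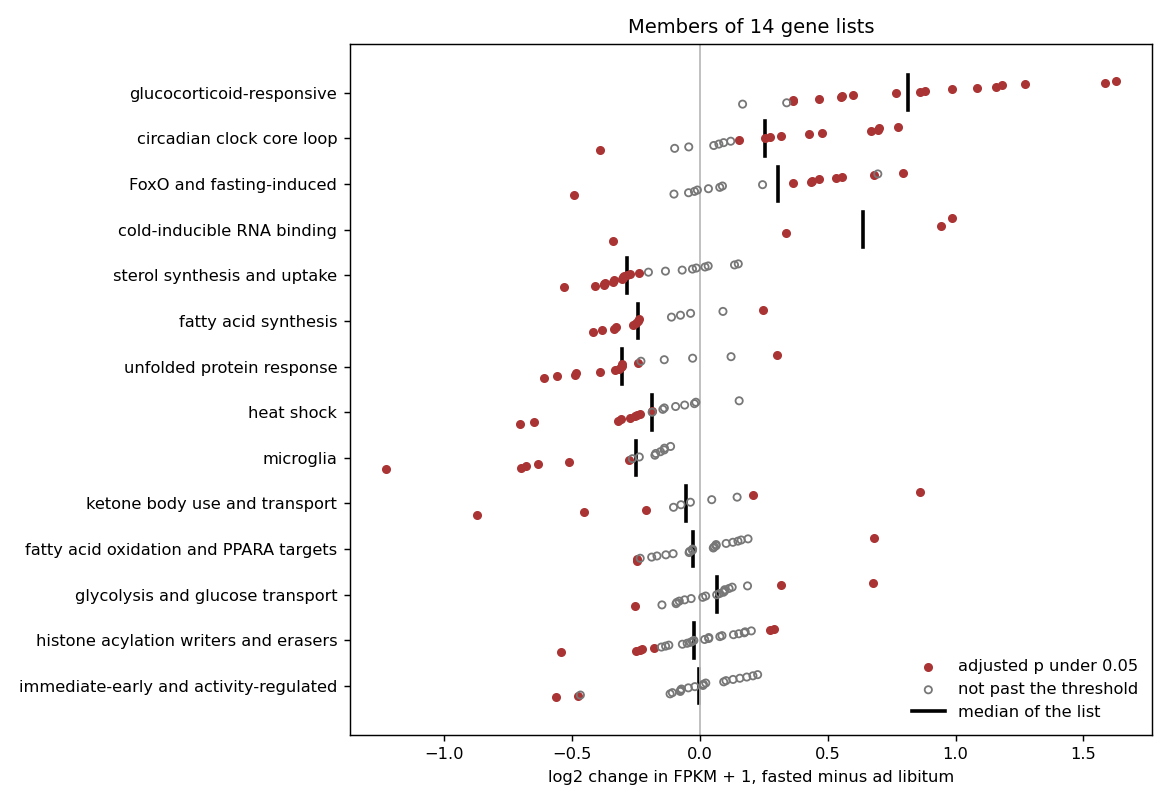
Log2 change in FPKM + 1, fasted minus ad libitum (x axis), of the measured members of 14 gene lists (y axis), 1 point per gene; filled points passed the adjusted p threshold of 0.05, open points did not, and black bars mark the medians. The median of the glucocorticoid-responsive list lies at 0.81 and that of the unfolded protein response list at -0.31.

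Genes of sterol synthesis and uptake fell in 14 of 23 cases and rose in 0 (15 and 1 adjusted over the list alone, and also with the replicate block). Hmgcs1, the synthase at the entry to the mevalonate pathway, went from 76.2 FPKM ± 2.56 (SD, n = 4) to 52.4 ± 2.03 (SD, n = 4), a log2 change of -0.53. Nsdhl and Sqle had log2 changes of -0.41 and -0.34. The set moved down (camera adjusted p = 4.17e-04; adjusted p = 0.334 with an estimated correlation). Of 13 fatty acid synthesis genes 8 fell and 1 rose, also adjusted over the list alone. Elovl5, Acss2, Me1 and Scd1, which act in chain elongation, acetyl-CoA and NADPH supply and desaturation, had log2 changes of -0.42, -0.38, -0.34 and -0.26. The set moved down (camera adjusted p = 0.00873; adjusted p = 0.576 with an estimated correlation).

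Genes of the unfolded protein response of the endoplasmic reticulum, chaperones and others, fell in 11 of 16 cases and rose in 1 (12 and 2 adjusted over the list alone). Calr, which encodes the calcium-binding chaperone calreticulin, went from 201.3 FPKM ± 14.8 (SD, n = 4) to 131.6 ± 9.75 (SD, n = 4), a log2 change of -0.61. The disulfide isomerase genes Pdia4 and Pdia6 had log2 changes of -0.56 and -0.48 and Hsp90b1 of -0.39. The set moved down (camera adjusted p = 4.17e-04; adjusted p = 0.803 with an estimated correlation). Heat shock genes fell in 9 of 17 cases and rose in 0 (10 and 0 adjusted over the list alone). Chordc1 had a log2 change of -0.70, Hsph1 of -0.65, Hspa8 of -0.32 and Stip1 of -0.27. The set moved down (camera adjusted p = 0.00153; adjusted p = 0.480 with an estimated correlation).

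Microglial markers fell in 6 of 14 cases and rose in 0 (7 and 0 adjusted over the list alone). Beside Fcrls, which went from 9.317 FPKM ± 1.501 (SD, n = 4) to 3.38 ± 0.307 (SD, n = 4), the fractalkine receptor gene Cx3cr1 had a log2 change of -0.70, Aif1 of -0.68 and the purinergic receptor gene P2ry12 of -0.64. The complement genes C1qa, C1qb and C1qc were at -0.17, -0.18 and -0.11 and did not pass the test (adjusted p = 0.33, 0.265 and 0.455). C1qb passed with the replicate block (adjusted p = 0.0291), and without ad libitum replicate 4 both C1qb and C1qc did (adjusted p = 0.0212 and 0.0163). The set moved down (camera adjusted p = 3.49e-04; adjusted p = 0.845 with an estimated correlation).

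Ketone body use and transport did not move as a set (camera adjusted p = 0.857): of 10 measured genes 2 rose and 3 fell, also adjusted over the list alone. Slc16a1, which encodes the monocarboxylate transporter MCT1, rose by 0.21 (adjusted p = 0.0248), a call that ended without ad libitum replicate 1, fasted replicate 2 or fasted replicate 4 (adjusted p = 0.0646, 0.0595 and 0.0675). Oxct1, the transferase that activates ketone bodies for use, went from 82.6 FPKM ± 3.23 (SD, n = 4) to 60.2 ± 4.71 (SD, n = 4), a log2 change of -0.45. Bdh1, the dehydrogenase that interconverts beta-hydroxybutyrate and acetoacetate, was at 15.3 FPKM ± 0.943 and 15.9 ± 1.80 (SD, n = 4 each), a log2 change of 0.05 that did not pass the test (limma adjusted p = 0.696).

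The other lists did not move as sets by camera. Among genes of fatty acid oxidation 1 of 21 rose and 2 fell, also adjusted over the list alone, and 3 rose and 4 fell with the replicate block (camera adjusted p = 0.81). Ucp2, which encodes a mitochondrial carrier, rose by 0.68, Hadha was at -0.25, and Decr1 at -0.25 (adjusted p = 0.0266) lost its call when any of ad libitum replicates 1, 2 and 3 or fasted replicate 4 was left out (adjusted p from 0.0515 to 0.0743). Among genes of glycolysis and glucose transport 2 of 19 rose and 1 fell, also adjusted over the list alone, and 4 rose and 2 fell with the replicate block (camera adjusted p = 0.338): the glucose transporter gene Slc2a1 rose by 0.68, from 19.7 to 32.2 FPKM, Ldha was at -0.25, and Pfkfb3 at 0.32 (adjusted p = 0.0196) lost its call without ad libitum replicate 1, 2 or 3 (adjusted p from 0.0520 to 0.0531). Among writers and erasers of histone acylation 2 of 25 rose and 5 fell (3 and 5 adjusted over the list alone, 7 and 6 with the replicate block; camera adjusted p = 0.908). The deacetylase genes Hdac9 and Hdac6 had log2 changes of -0.54 and -0.23, the acetyltransferase gene Crebbp rose by 0.29, and Hdac2 at -0.18 (adjusted p = 0.0193) lost its call without ad libitum replicate 2 or 3 or fasted replicate 3 (adjusted p from 0.0511 to 0.0614). Of 20 immediate-early and activity-regulated genes 2 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.908), Nptx2 with a log2 change of -0.56 and Jun with -0.48. With the replicate block 3 fell and 0 rose (camera adjusted p = 0.904). Without ad libitum replicate 1 the list moved down (camera adjusted p = 0.0286), in a fit that kept fasted replicate 1. Fos was lowest in replicate 1 of both groups (24.6 FPKM fed, 30.2 fasted). That fall of the list thus cannot be told apart from the effect of unequal replicate numbers. Fos was at 54.2 FPKM ± 20.5 and 49.6 ± 15.02 (SD, n = 4 each; limma adjusted p = 0.908), and the neuropeptide gene Npy at 164.9 ± 21.97 and 151.5 ± 12.4 (SD, n = 4 each; limma adjusted p = 0.404).

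Markers of other cell types and neighbouring tissues did not move as sets by camera, and fibroblast and meninges came nearest to the threshold (camera adjusted p = 0.0726). Of the neuronal markers, 1 of 12 excitatory markers rose and 5 fell, and 1 of 11 inhibitory markers fell (1 rose and 1 fell with the replicate block). Of 12 astrocyte markers 2 rose and 4 fell. In the oligodendrocyte lineage 3 of 14 mature markers rose and 3 fell, 2 of 10 newly formed markers rose and 2 fell, and 4 of 10 precursor markers fell. Of the vascular and border markers, 4 of 12 fell for endothelium (4, and 2 rose, adjusted over the list alone or with the replicate block), 2 of 8 for pericyte and smooth muscle and 4 of 10 for fibroblast and meninges. The 6 erythroid and 7 hippocampal markers had no call, with 0 and 1 at an unadjusted p under 0.05; with the replicate block 2 hippocampal markers fell. Of 7 striatal markers 1 rose and 1 fell, and of 10 thalamic markers 1 rose and 2 fell. Except for endothelium, these counts were the same adjusted over the list alone. For the inhibitory, erythroid and thalamic markers median and mean lay under 0 while camera pointed up.

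The remaining functional lists did not move as sets by camera either. None of 44 cytosolic ribosomal protein genes, 25 proteasome genes or 3 cell division genes was called by limma without the replicate block, with single-gene adjusted p at or above 0.05; at an unadjusted p under 0.05 there were 2, 1 and 1. With the block 1 ribosomal gene rose and 8 fell, 5 proteasome genes rose and 0 fell, and 0 cell division genes were called. Of 30 nuclear genes of oxidative phosphorylation 2 fell, 0 adjusted over the list alone, and with the block 2 rose and 5 fell. At the synapse 1 of 19 glutamate receptor genes rose and 7 fell, and 4 of 16 genes of GABA receptors and synthesis fell (5 adjusted over the list alone; with the block 1 rose and 7 fell). Of 14 neuropeptide genes 2 fell, and with the block 1 rose and 3 fell. Of 12 glycogen genes 2 rose and 4 fell, of 16 genes of the ATF4 amino acid response 1 rose and 4 fell (1 and 5 adjusted over the list alone), and of 16 NRF2 antioxidant genes 1 rose and 3 fell (1 and 5 with the block). Of 20 autophagy and lysosome genes 1 rose and 3 fell (2 and 4 with the block), and of 16 growth factor and mTORC1 genes 3 rose and 4 fell. Of 16 basement membrane and collagen genes 3 fell (with the block 2 rose and 4 fell), of 10 interferon and antigen presentation genes 3 fell (4 adjusted over the list alone, 5 with the block) and of 5 cytokine signalling genes 2 fell. The other counts in this paragraph were the same adjusted over the list alone. For oxidative phosphorylation, growth factor and mTORC1 genes and histone acylation, median and mean lay under 0 while camera, which compares with the other genes, pointed up. For fatty acid oxidation only the median lay under 0. Of the 43 lists tested 9 moved with the preset correlation, 4 up and 5 down, and 0 with an estimated correlation (4 at an unadjusted p under 0.05). The estimated correlation of the 9 ran from 0.0237 (circadian core loop) to 0.6992 (microglia). For the core loop it was near the preset 0.01, yet camera's unadjusted p went from 1.65e-05 to 0.00752. With an estimate, camera rests on the few residual degrees of freedom of the 8 libraries, so a lost call need not mean a high correlation.

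The p-values measure the spread between libraries that the labels present as separate replicates, and no label says how many mice gave each library. Other splits of the 8 libraries into 4 and 4 gave 9 or more moved lists in 15 of 35 cases, the real split included. The number of moved lists with a preset correlation thus did not part fasted from fed libraries better than many other groupings of them. For single genes no other split gave more than 8 changed genes.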

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

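Each test of an explanation in this part was chosen after the result it bears on was seen, except that of GC content and transcript length and the count of moved lists over other splits.

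In 178 groups of 4 libraries tested on named genes and library measures, 15 had 1 library far from the other 3, where chance gives about 1 in 20, or 8.9. The FPKM total of ad libitum replicate 2 was 640016.8, with the others between 254085.8 and 308028.1. Without symbols that begin with Mir, Snor, Gm or a few similar prefixes it was 278257.6, with the others between 248595.8 and 275867.0. The excess thus stood mostly on such symbols and not on all genes. Fasted replicate 1 was highest for Sult1a1 (13.5 FPKM, others 10.7 to 11.2), Hdac2 (35.8, others 32.7 to 33.1) and Stip1 (57.1, others 51.9 to 52.6). Fasted replicate 2 was lowest for Slc16a7 (2.27 FPKM, others 2.93 to 2.98), Pdk4 (3.78, others 4.29 to 4.36) and Hsph1 (44.7, others 50.9 to 51.3). Ad libitum replicate 2 was lowest for Pdk4 (2.75, others 2.83 to 2.85) and highest for Bhlhe41 (4.25, others 3.89 to 3.92). Ad libitum replicate 4 was lowest for Scd1 (32.7, others 36.4 to 36.5) and Rbm3 (48.1, others 57.0 to 58.1) and highest for Hsp90b1 (141.0, others 132.0 to 133.0). Ad libitum replicate 1 was highest for Alox12b (1.69, others 1.14 to 1.17), fasted replicate 3 for Aif1 (1.34, others 0.984 to 1.03), and fasted replicate 4 was lowest for Igfbp5 (22.3, others 29.0 to 30.1).

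The real split of the 8 libraries gave 3198 changed genes, and 1 of the 35 splits, the real one, gave as many. The highest of the others was 8, for the split of odd against even numbers. However, 1 of 35 is the smallest share that 35 splits can give. The other splits also mix fasted and fed libraries, which widens the spread within their groups and lowers their counts. The low counts there thus do not by themselves exclude chance. Of the 8 splits that part all 4 pairs, the highest other gave 1, though 1 of 8, or 0.125, is the smallest share that 8 splits can give. For the lists chance cannot be excluded: the real split moved 9 lists, 15 of the 35 splits moved as many, and the highest other moved 14. Among the 8 splits that part all pairs 4 moved as many, and the highest other moved 12. Among the 9 moved lists, the glucocorticoid-responsive, FoxO, fatty acid synthesis and cold-inducible lists had a smaller p in the real split than in any other (1 of 35 splits each). Sterol synthesis had as small a p in 2 splits, the unfolded protein response and heat shock in 3 each, the circadian core loop in 4 and microglia in 6.

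More changed genes were lower (2015) than higher (1183) in fasted cortex, 63% of the changed genes. The percent was 52.9 under median-ratio scaling, 51.6 under quantile scaling, the lowest of the 3 scalings, and 57.9 under equal-sum scaling, and with offsets for GC content and length 49.9. It dropped mainly because more genes were called higher (1430 to 2228), while the number called lower was 1909 to 2217. The offsets also level the libraries as a whole, so their effect cannot be assigned to GC content or length. Differences in scaling, bias by GC content or length and a true small shift of most genes cannot be told apart by these values as the source of the excess.

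The log2 changes of the microglial markers were unequal, with a pseudocount of 0.1 from -1.43 for Fcrls to -0.12 for C1qc. Of the 14 markers 6 were called lower, and C1qc was not among them. If the share of microglia alone had dropped, the 14 markers would fall alike. With each marker set against its library's mean over the markers, the groups differed (exact permutation test, p = 0.0286, the smallest that 70 assignments can give). Within the 4 pairs of replicate numbers the exact sign-flip test gave p = 0.125, the smallest it can give, so a lower share with each cell unchanged and a change within microglia cannot be told apart with these few pairs. A lack of scaling as the whole cause is argued against: the markers' median log2 change was still -0.2218 under the scaling that brought it nearest to 0, and under each of the 3 scalings the libraries' means over the markers differed between the groups (exact permutation test, p = 0.0286), while limma with the block called 8 or 9 of the markers lower and 0 higher. As 6 of 35 splits gave the list as small a p, chance movement of the list stays open.

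Ad libitum replicate 3 lay between the other libraries in sex-linked transcripts. Xist was at 32.2 FPKM there, against 74.5 and 77.5 in ad libitum replicates 2 and 4 and 0.0387 in replicate 1, and Eif2s3y at 10.2 FPKM against 18.9 in replicate 1. The median of 4 Y-linked genes was 0.549 of the level in replicate 1 and Xist was 0.424 of the mean of replicates 2 and 4, adding up to 0.973. This is what a mix of male and female tissue in that library would give, which may have arisen by pooling animals or by mixing material at a later step; a single mouse of either sex with a wrong label would not give both. No biological explanation was tested.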

How the results depend on the processing

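The scalings, the term for odd and even numbers, the exclusion of symbols on several rows, the estimated correlation with the block and the tests within replicate numbers for library measures and microglial markers were chosen after seeing the data. The 3198 changed genes were 2220 to 5049 over all settings. No gene called in common changed direction in any of them, which is nearly assured as the fits share their libraries. With the replicate number as a block 4506 changed (1773 higher, 2733 lower), of which 3185 were shared; with block and GC and length offsets 5049 (2564 higher); with the offsets alone 2228 were higher and with quantile scaling 1792. Leaving out each library gave 2247 to 3768 changed genes, 841 to 1196 higher and 1406 to 2572 lower, and 9 to 12 lists. The 9 moved lists became 0 with an estimated correlation, 0 with the estimated correlation and block, 13 by fry's directional test and 34 by its mixed test, which asks for change in either direction. The 13 were the 9 lists and, all down, GABA receptors and synthesis (fry adjusted p = 0.00667), cytokine signalling (0.00741), oligodendrocyte precursor (0.006) and pericyte and smooth muscle (0.0195). The cause of the other shifts was not tested. Over left-out libraries the group difference in genes at 1 FPKM or more ran from -115.833 to -53.1667, the former without ad libitum replicate 4 (exact permutation p = 0.0286), that in depth from -308333 to 958333 fragments, reversed without fasted replicate 3, that in the FPKM total from -133542 to -4898.68 and that in the share of the 10 most abundant genes from -4.49833 to -1.27833.

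Reversals were seen for results that had not passed the test. Npy went to 0.0045 on the log2 scale with GC and length offsets, with or without the block. Over left-out libraries Fos ranged from -0.4101 to 0.1395 and the immediate-early list's median from -0.2288 to 0.1399. Leaving out a library unbalances the replicate numbers between the groups, an effect that these ranges include. The set direction turned from up by camera to down by fry for fatty acid oxidation (median log2 change -0.0287), histone acylation (-0.0236), nuclear oxidative phosphorylation (-0.018), inhibitory neuron (-0.032), erythroid (-0.046) and thalamus (-0.001), and by camera with the block for inhibitory neuron. It also turned for histone acylation with no filter (-0.0236) and a filter at 5 FPKM (-0.0265). The median of all tested genes was -0.0244. The block ended the call of Ccl21b and added those of C1qb and Csf1r, and changed no other call of a gene named in the text and no camera call of a list. It raised the number of called members of several lists by over 1.5 times, most for ribosomal proteins, from 0 to 9. Not run were the alternatives that need read counts (other size factors and filters on counts, other count models and a surrogate variable) and the removal of mitochondrially encoded genes, of which the table has 0. Depth limits low genes, as at 1 FPKM a transcript of 2 kb rests on 35.2 to 42.8 fragments by the uncertain estimate of depth. In simulation 6.5% of genes changed 1.2-fold were called, with 200 genes changed and drawn at all levels. That share bears neither on depth nor on the sensitivity in the data, where 3198 genes were called and the adjusted threshold was less strict.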

Other observations

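The genes in this paragraph, except Igfbp5, were chosen after their values were seen. Hsf1, the transcription factor that drives heat shock genes, was lower, as were 9 of the 17 genes of that list. It went from 10.8 FPKM ± 0.662 (SD, n = 4) to 6.64 ± 0.384 (SD, n = 4), a log2 change of -0.62 (limma adjusted p = 0.000103). Pnpla2, which encodes the first lipase of triglyceride breakdown, rose from 4.96 FPKM ± 0.310 to 9.91 ± 1.41 (SD, n = 4 each), and Mfsd2a, which encodes the carrier of lysophospholipid-bound docosahexaenoic acid at the blood-brain barrier, from 6.03 ± 0.614 to 12.01 ± 1.90 (SD, n = 4 each). Slc38a5, a glutamine carrier gene, went from 1.63 to 0.479 FPKM, a log2 change of -0.83. Ugt8a, which encodes the galactosyltransferase of myelin lipid synthesis, had a log2 change of -0.71, while the mature oligodendrocyte list did not move. Itih3 rose by 0.84, and Igfbp5 had a log2 change of -0.50.

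An interaction of feeding with odd and even replicate numbers was called for 1 gene (264 at an unadjusted p under 0.05), BC002163. Its symbol stands on 2 rows. One row held 1.35, 93.8, 0.741 and 85.2 FPKM in ad libitum replicates 1 to 4 and the other 89.6, 0.682, 71.6 and 1.33, so that nearly all of the signal stood on 1 row in each library, while the sums of the rows were 91.0, 94.5, 72.3 and 86.5 FPKM; in the fasted libraries the sums were 78.7, 60.8, 71.7 and 78.4 FPKM.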
